A study of Mus musculus with 2 samples.

How the data were processed

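The study followed mouse embryonic stem cells that carry GFP at the Brachyury (T) locus as they formed embryoid bodies, which are floating aggregates in which stem cells start to differentiate. RNA of single cells was profiled in droplets with 3' tag libraries, in 1 library at day 4 and 1 library at day 6. Per the labels' protocols, cells were grown on feeder cells with serum and LIF, placed at day 0 in serum-free suspension culture at 75000 cells per mL, and given Noggin (150 ng/mL), Wnt3a (25 ng/mL) and activin A (9 ng/mL) from day 2 for 48 h. The day 6 culture then received bFGF (10 ng/mL) for a further 48 h. Cells were dissociated, passed through a 30 µm strainer, and 10000 cells were taken into library preparation. Each library was assigned to its day by the time label of its sample.

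The submitters' processing notes name Cell Ranger, STAR and the mouse build mm10, without versions. The deposited values are scores per gene and cell: they are continuous, never negative, reach 7.92 at day 4 and 8.71 at day 6, and are not whole counts. The log base, the scaling and any smoothing are not given in the sources used here. Both tables list the same genes by symbol. Values of 0 made up 0.0319% of the entries at day 4 and 0.0362% at day 6. Most of those zeros lay in 2 cells per library that were mostly 0, and 3 further cells at day 6 held a zero. Because no counts were at hand, the depth of each cell is unknown, and intervals that need counts were not computed for gene values.

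The tests planned before the data were examined assumed counts or linear values: folds with Poisson intervals, the share of cells with a T molecule and cells thinned to equal depth. None of these could be run as planned on the scores. A T value above 0 was present in 5060 of 5062 cells at day 4 and 4840 of 4842 at day 6, so that share carried no information. The plan was to back-transform log values first, but the log base is not given, so this became an alternative. The mean of each gene over the cells of a library was used instead, with the difference of the means, day 6 minus day 4, and the SD over cells. The SD describes the spread between cells of 1 library, and cells are not replicates of a culture. With 1 library per day there is no replicate check, so no p-value, standard error or tested number of changed genes is given, and every difference compares these 2 libraries. Genes were counted by a size rule of 0.25 in the difference of means. The use of differences, this size rule and the level for list members were settled after the values had been looked at, and the counts at 0.1, 0.25 and 0.5 had been seen before 0.25 was taken.

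The genes named were chosen by a rule fixed before the data were examined: T first, the 12 highest and the 12 lowest by the ratio of the 2 means among the 5000 genes with the highest mean (without mitochondrial, ribosomal and unnamed gene models), the 4 members of each gene list with the widest ratio, and the leading genes of each cluster. The ratio served to rank genes only. The rule had foreseen a ratio of counts or of linear means, and the ratio of mean scores was taken in its place once the values had been looked at. Other genes named are list members or markers picked after their values had been seen. For the correlations with T, the 3 highest and 3 lowest lists and the 5 highest genes and the lowest gene of each library are given, with general pluripotency and Shh, a choice also made after the values had been seen. The 43 lists (15 of cell type markers and 28 of pathways and other groups) were also fixed beforehand. A member entered where its mean was at least 0.02 in either library, and a list needed 3 such members, which 40 lists had. For the correlations with T, the mean had to reach 0.02 in the library concerned, and T itself was left out. Each list's median difference was placed among the medians of 10000 random lists of the same size, matched on mean level in 40 bins. The resulting percentile describes these libraries and is not a p-value.

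Cells were clustered within each library with the Leiden algorithm (leidenalg 0.10.2, python-igraph 0.11.9, resolution 0.8, seed 0) on a shared-neighbour graph of 15 neighbours from 30 principal components of 2000 variable genes. Genes were ranked within a cluster by the ratio of its mean to that of the other cells, with 0.02 added to both. A cluster took the name of a marker class when that class had at least 3 markers among the 30 leading genes, more than any other class, and no other class had more among the first 10. A further condition, a mean standardized difference of the class markers of at least 0.5, was set after the clusters had been seen, because the fixed rule called a cluster led by Gbx2, Vgll3, Timp4 and Olig3 primitive streak-like. It left this 1 cluster unnamed, cluster 4 of day 4 with 7.57% of the cells, and none at day 6. Shares of cells have exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. Cells were not checked for doublets, since the callers need counts, and no cells were left out except in the alternative described next.

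Alternatives were day 6 rescaled by the median ratio of the means, each cell scaled to the same total (with and without ribosomal and mitochondrial genes), values back-transformed as natural logs, quality-filtered cells, medians over cells, day 6 means quantile-matched to day 4, other levels for list members, other clustering settings, and partial or Pearson correlations. With no replicates, a list was said to hold where it kept its sign and its place inside or outside the central 95% of random lists, a difference of means where it stayed within 1.5 times, a correlation where it stayed within 0.1, and a share where it stayed in its binomial interval. The quality filter kept cells within 3 median absolute deviations of the median log total, under 10% mitochondrial value and not mostly 0. It removed 229 day 4 cells and 38 day 6 cells. Steps were tested on simulated data made from the day 4 means, with relative scatter drawn from single values of abundant day 4 genes. Genes were drawn independently, and both simulated libraries had the same means apart from the changed genes. These checks therefore cover neither the shift between the 2 real libraries nor the wider relative scatter of low genes. For the comparison of means, the direction was recovered for 100% of the genes whose mean was multiplied by 0.25, 0.5, 2 or 4 (50 genes each), and 0% of 15364 unchanged genes passed the size rule. Each simulated mean averaged as many independent draws as the library had cells, so both results were close to fixed in advance. Among 200 unchanged lists, 5% lay outside the central 95%, the share that lists drawn at random give by design. These outcomes check the computation only. Clustering returned 4 simulated groups exactly, but split cells simulated with no groups into 3 clusters, so a cluster by itself does not show a cell type. Gene positions come from the GENCODE M21 annotation of GRCm38, the assembly known as mm10. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0.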

Results

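Single-cell values were compared between embryoid bodies at day 4, after primitive streak induction with Wnt3a, activin A and Noggin, and at day 6, after 48 h in bFGF. The day 4 library held 5062 cells and the day 6 library 4842 cells, the numbers the submitters state. The summed value of a cell had a median of 3637 at day 4 (quartiles 3260 and 3893) and 2966 at day 6 (quartiles 2523 and 3283). There was 1 library per day and no replicate, so each SD is over cells. All values are deposited scores.

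The first comparison asked how expression in the whole culture differed between the days. T (Brachyury), the transcription factor that marks the primitive streak and notochord and carries the GFP reporter, had a mean of 0.148 (SD 0.208) at day 4 and 0.0716 (SD 0.157) at day 6. T lies on chromosome 17 from 8434423 to 8442496 (GRCm38, plus strand, protein coding). Its median over cells was 0.0675 at day 4 and 0.0207 at day 6, and its 95th percentile was 0.564 and 0.322. Genes of pluripotent cells and of the epiblast were lower at day 6. Of the genes named by rank, those higher at day 6 included the neuronal RNA-binding protein genes Elavl3 and Elavl4, the tubulin genes Tubb3 and Tubb2a and the neural transcription factor gene Pou3f2.

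Most genes had a lower mean at day 6 (11181 genes, 71.8%), and the median log2 ratio of the means was -0.34 among the 4169 genes with a mean over 0.2. Changes are therefore also given relative to this shift, after day 6 was divided by the median ratio of 0.792. As deposited, 666 genes were at least 0.25 higher at day 4 and 66 at least 0.25 higher at day 6. After the rescaling, the split turned, with 135 genes higher at day 4 and 335 at day 6. The division raises each day 6 mean in proportion to its level, so abundant genes can pass 0.25 through it alone. Cytosolic ribosomal proteins, with median means of 2.78 and 2.69, went from 30 to 67 of 80 members higher. The turned split therefore does not show that more genes rose than fell. The 24 genes named by rank kept their direction in all 7 alternative settings.

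Pou5f1, the core pluripotency factor (chromosome 17, 35506018 to 35510772), had a mean of 0.82 (SD 0.808) at day 4 and 0.126 (SD 0.24) at day 6, a difference of -0.695 and of -0.662 after rescaling. Dppa5a, an RNA-binding protein of pluripotent cells, had means of 0.942 and 0.167. The Nodal co-receptor gene Tdgf1 had 0.356 and 0.0449, the chromatin factor gene Utf1 0.424 and 0.0579, and L1td1 0.405 and 0.0591. The epithelial adhesion gene Epcam had 0.78 and 0.142, and the tight junction gene Cldn7 had 0.334 and 0.0562. Car2, Tmem238, Trh, Tcea3 and Pim2 completed the 12 lowest genes, with differences between -0.503 for Car2 and -0.232 for Tmem238.

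Of the 12 highest genes at day 6, Elavl4, a neuronal RNA-binding protein gene (chromosome 4, 110203722 to 110351909), had a mean of 0.164 (SD 0.319) at day 4 and 0.516 (SD 0.599) at day 6, a difference of 0.352 and of 0.487 after rescaling. Its relative Elavl3 had means of 0.124 and 0.365. Map2, a microtubule protein of neurons, had 0.0905 and 0.264, the neuronal tubulin gene Tubb3 0.205 and 0.423, and the splicing regulator gene Srrm4 0.0979 and 0.258. The membrane protein gene Gpm6b had 0.217 and 0.531, and the neural transcription factor gene Pou3f2 had 0.242 and 0.497. Tshz2, Sparcl1, Tagln3, Tubb2a and Mllt11 were the others, with differences between 0.119 for Tubb2a and 0.256 for Tagln3.

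**Figure D1:**
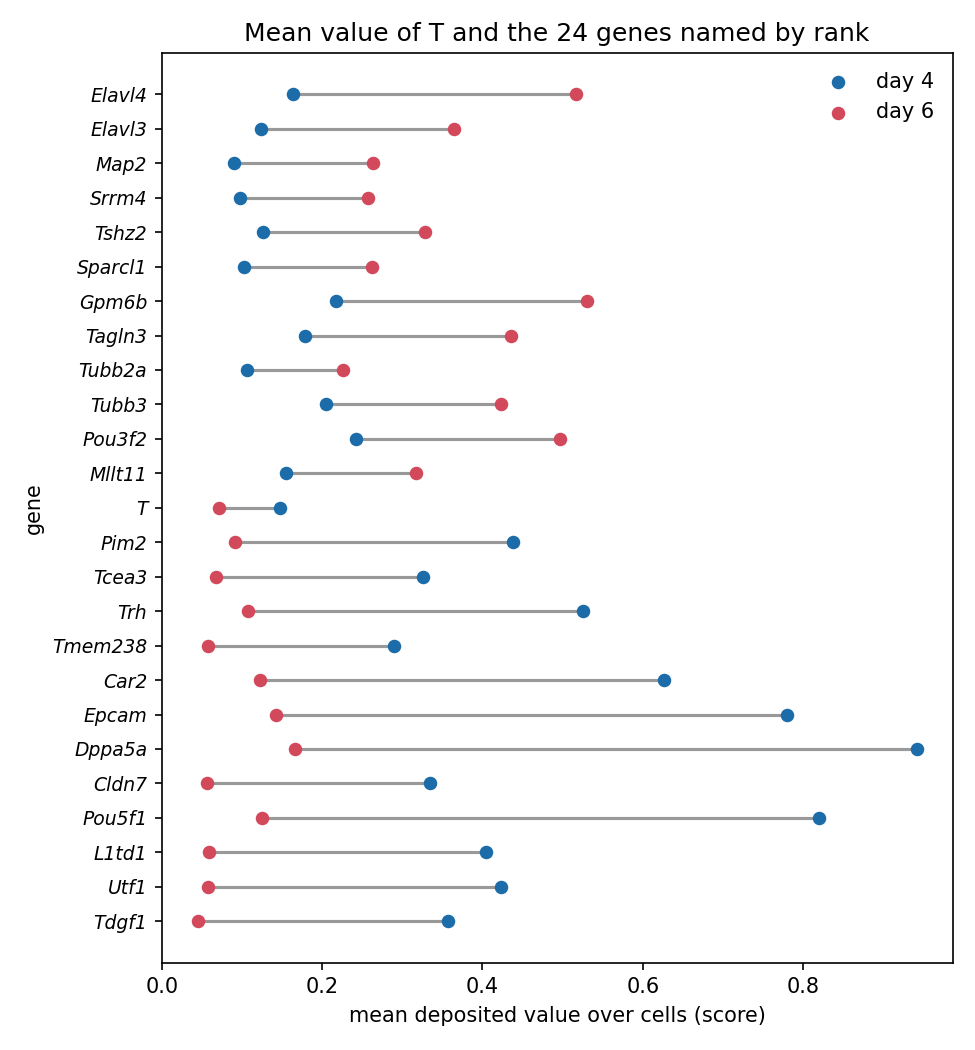
Mean deposited value over cells (x axis, score) of T and the 24 genes named by rank (y axis) in the day 4 library (blue, 5062 cells) and the day 6 library (red, 4842 cells), with a line joining the 2 means of each gene. Pou5f1 lies at 0.82 and 0.126, and Elavl4 at 0.164 and 0.516.

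Among the fixed lists, 9 had a median difference below the central 95% of matched random lists and 6 above it. All 10 post-implantation epiblast genes were lower at day 6, before and after rescaling, with a median difference of -0.266 (percentile 0). Fgf5 had means of 0.222 and 0.0324, and the de novo methyltransferase gene Dnmt3b 0.808 and 0.205. All 12 general pluripotency genes were lower, 11 of them after rescaling (median -0.158, percentile 0), and all 10 naive pluripotency genes were lower, 9 after rescaling (median -0.0518, percentile 0.04), among them Zfp42 with 0.234 and 0.0389. All 14 epithelial genes were lower in both scalings (median -0.136, percentile 0), including Rab25 with 0.15 and 0.0195 and Esrp1 with 0.118 and 0.0173.

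Primitive streak genes were lower for 8 of 9 members in both scalings (median -0.0492, percentile 0.21). The T-box gene Eomes had means of 0.0403 and 0.007, Nodal 0.0676 and 0.0119, and Fgf8 0.214 and 0.0444. Targets of Nodal and activin were lower for 9 of 9 members, 8 after rescaling (median -0.0492, percentile 0.06), with Lefty2 at 0.0481 and 0.00723. These 2 lists share members. Wnt targets were lower for 9 of 10 members as deposited and for 5 after rescaling (percentile 9.43), with Lef1 at 0.279 and 0.0851 and Axin2 at 0.174 and 0.0799. The 22 S phase genes were all lower, 19 after rescaling (median -0.189, percentile 0.4), for example Mcm5 with 0.662 and 0.279.

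The lists above the central 95% were those of neuroectoderm, the Notch pathway, Hox paralogs 1 to 4, mesenchymal genes, imprinted genes and paraxial mesoderm. Of 10 neuroectoderm genes 7 were higher at day 6, and 8 after rescaling (median 0.0214, percentile 100). Pax6 had means of 0.255 and 0.371, the Notch effector gene Hes5 0.502 and 0.798, and Lhx5 0.0406 and 0.124. Of 9 Notch pathway genes 8 were higher (median 0.0514, percentile 100), with the ligand gene Dll1 at 0.0987 and 0.208. All 5 Hox genes used were higher in both scalings (median 0.0543, percentile 99.97), with Hoxa2 at 0.195 and 0.305 and Hoxb4 at 0.0337 and 0.088. Of 8 mesenchymal genes 6 were higher, and 7 after rescaling (median 0.0891, percentile 100), among them Vim with 0.702 and 1.05 and Zeb2 with 0.307 and 0.468, genes that neural progenitors also express. Of the 6 paraxial mesoderm markers used, 4 were higher (median 0.0373, percentile 99.97), but with no minimum level the median over 13 members was 0.000518. These were Dll1, Dll3, Lfng and Pax3, which neural progenitors express as well, while Tbx6, a marker of presomitic mesoderm, had means of 0.00276 and 0.00163, at the 5.83 and 1.99 percentiles of all genes, and was named after its values were seen. Of 15 imprinted genes 9 were higher and 11 after rescaling (median 0.0228, percentile 99.98), with the cell cycle inhibitor gene Cdkn1c at 0.438 and 0.795 and Impact at 0.494 and 0.303.

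**Figure D2:**
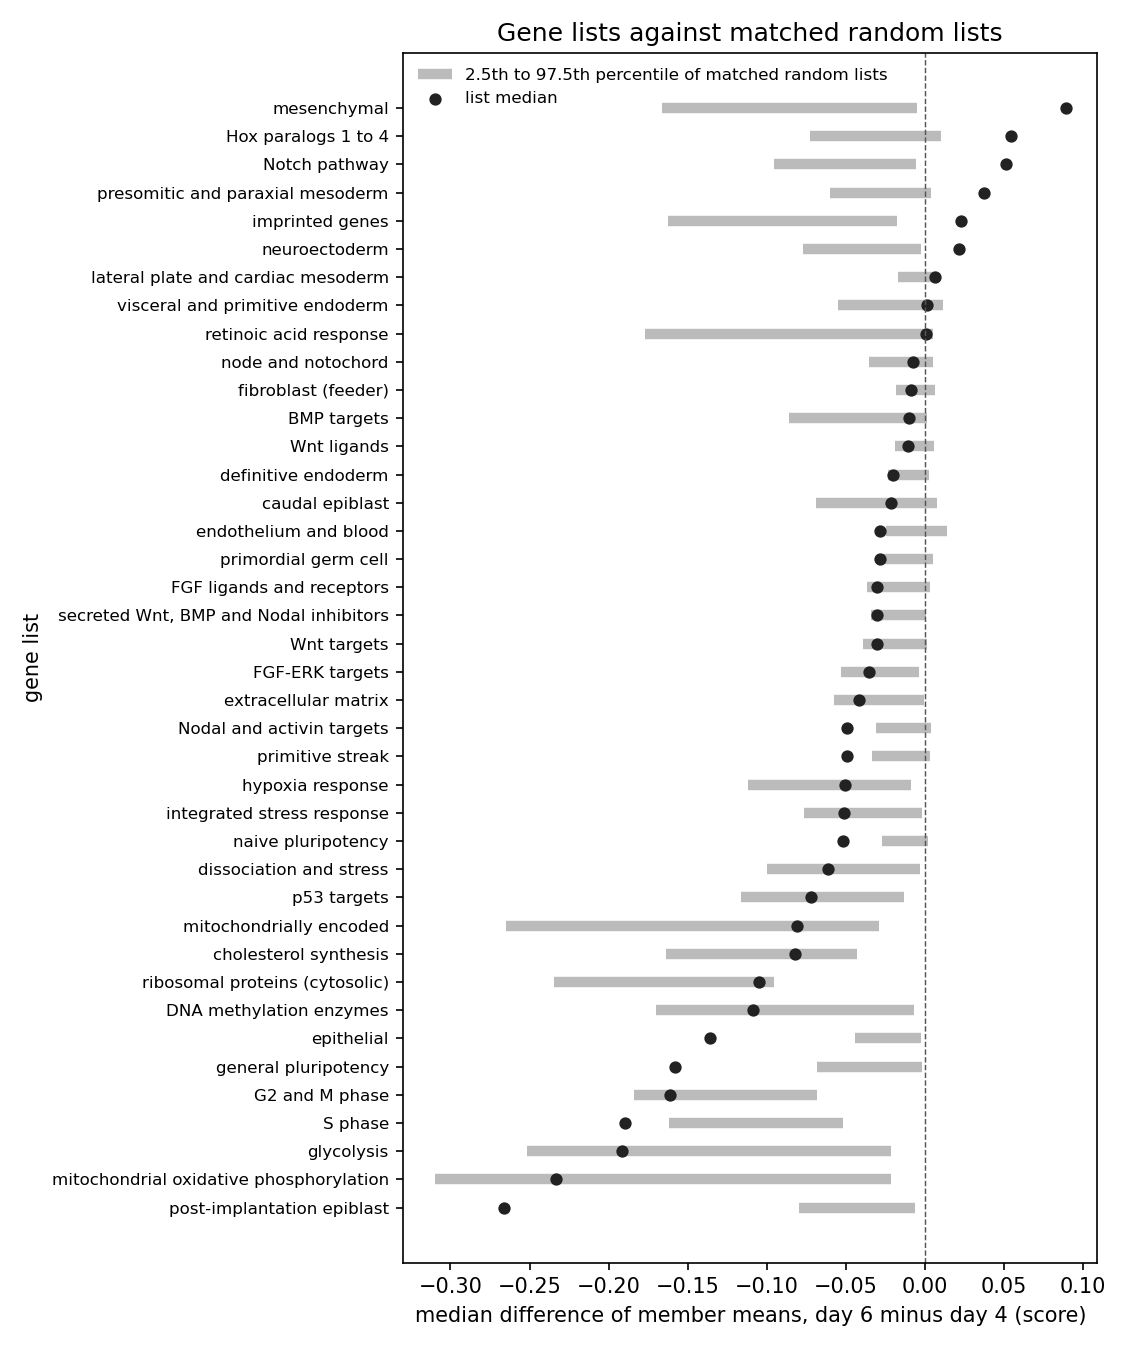
Median difference of the member means, day 6 minus day 4 (x axis, score), for the 40 gene lists with at least 3 members used (y axis). Points are list medians and grey bars span the central 95% of 10000 matched random lists. The post-implantation epiblast list lies at -0.266 and the mesenchymal list at 0.0891.

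Single markers of some other lineages were near the floor. Means of the endothelial receptor gene Kdr were 0.00453 and 0.00342, and those of the visceral endoderm gene Ttr were 0.00242 at both days. The definitive endoderm list had a median difference of -0.0202 (percentile 5.78, and 1.18 after rescaling), the node and notochord list -0.00769 (percentile 68.1, and a median of 0.00915 at percentile 79.8 after rescaling), the feeder fibroblast list -0.00864 (percentile 27.8) and the visceral endoderm list 0.00149 (percentile 91.2). Within the node list the members went both ways, with Shh at 0.0256 and 0.055 and Krt8 at 0.269 and 0.128. The germ cell list was lower for 6 of 6 members, 5 after rescaling (median -0.0286, percentile 1.43), which include Dppa3, a gene of naive pluripotent cells as well, and the blood and endothelium list for 3 of 3 (median -0.0282, percentile 1.59). Both came inside the central 95% by medians over cells (-0.00977 and -0.0115), the germ cell list also when back-transformed or quantile-matched, and the blood and endothelium list also with no minimum level. Sox2, a factor of pluripotent and neural cells, had means of 0.856 and 0.852. Kdr, Ttr and Sox2 were named after their values were seen.

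The second comparison asked which kinds of cells each library held. Clustering gave 16 clusters at day 4 and 20 at day 6. At day 4, clusters 1 and 2 were post-implantation epiblast-like and held 20% of the cells (95% interval 18.9% to 21.1%), with Pou5f1 means of 1.63 and 1.55. Clusters 6 and 13 were naive pluripotency-like and held 12.1% (11.2% to 13.1%), with Zfp42 means of 1.68 and 0.715. The mean standardized difference of the naive markers was 2.67 in cluster 6 but 0.832 in cluster 13. Cluster 13 also carried the epiblast gene Fgf5, at 0.349 against 0.0972 in cluster 6 and 0.456 in cluster 2. Cluster 11 was node and notochord-like and held 5.65% (5.03% to 6.32%), against 2.88% in this class when both libraries were clustered jointly. It had means of 0.51 for T, 0.17 for Shh and 0.854 for Krt8. The other 62.3% of day 4 cells were in unnamed clusters. They include cluster 4 (7.57%, 6.85% to 8.33%), led by Gbx2, Vgll3, Timp4, Olig3 and Fst with a T mean of 0.178, which the naming rule alone would have called primitive streak-like.

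Several unnamed day 4 clusters were led by genes of known patterns. Cluster 7 (353 cells) was led by Cer1, Sox17, Dkk1 and Gsc, genes of the anterior streak and endoderm, and had a T mean of 0.497. Cluster 3 (397 cells) was led by Hoxb1, Nkx2-9, Fgf3 and Hoxb2, with Hoxb2 at 0.683. Clusters 9, 10 and 12 (6.84%, 5.95% and 5.29% of the cells) had Hes5, Pax7 and Cyp26b1 among their leading genes, with Hes5 means of 1.49, 1.4 and 1.53. Cluster 14 (211 cells) was led by Nhlh2, Dcx and Ebf2, genes of young neurons, with a Tubb3 mean of 2.18. Clusters 5 and 15 (371 and 110 cells) had the lowest totals of the day 4 clusters, at 76.1% and 65.2% of the library median. Cluster 15 also had the lowest Malat1 mean (1.44), and what set these clusters apart was not tested.

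At day 6, cluster 8 was post-implantation epiblast-like with 5.64% of the cells (5.01% to 6.33%) and a Pou5f1 mean of 0.59. Cluster 16 was naive pluripotency-like with 2.62% (2.19% to 3.11%) and a Zfp42 mean of 0.939. The other 91.7% were in unnamed clusters. These shares depended on the clustering: with both libraries clustered jointly, 80 day 6 cells were epiblast-like and 70 naive pluripotency-like. Some other settings raised the epiblast-like share. Unnamed clusters 1, 3, 4, 5, 6, 7 and 15 held 606, 381, 379, 369, 285, 282 and 157 cells. Their means of the neuroectoderm marker Hes5 ran from 0.845 in cluster 1 to 1.63 in cluster 7, against at most 0.741 in the others. Those of Pax6 ran from 0.341 in cluster 1 to 0.84 in cluster 5, with 0.732 in cluster 17 outside this group. Both genes were picked here after their values were seen. Clusters 9, 11, 13, 17, 18, 19 and 20 were led by neuronal genes such as Nhlh1, Neurog1, Stmn4, Insm1, Nefm and Gap43. Their Tubb3 means ran from 0.764 in cluster 17 to 2.34 in cluster 13. Totals were low in clusters 10 and 20, at 64.6% and 63.6% of the library median, and also in clusters 19 (73.3%), 14 (74.7%) and 6 (78.5%). Clusters 10 and 20 also had the lowest Malat1 means, 1.71 and 1.93, against at least 3.72 in the other day 6 clusters. What set these 2 clusters apart was not tested. Cluster 12 (199 cells, 4.11%) was led by T, with means of 0.606 for T, 0.404 for Shh and 0.847 for Krt8. Cluster 2 (381 cells) shared Krt19, Vtn and Shh among its leading genes and had a T mean of 0.205. Shares are not compared between days, because the genes that define the clusters themselves differed between the libraries.

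**Figure D3:**
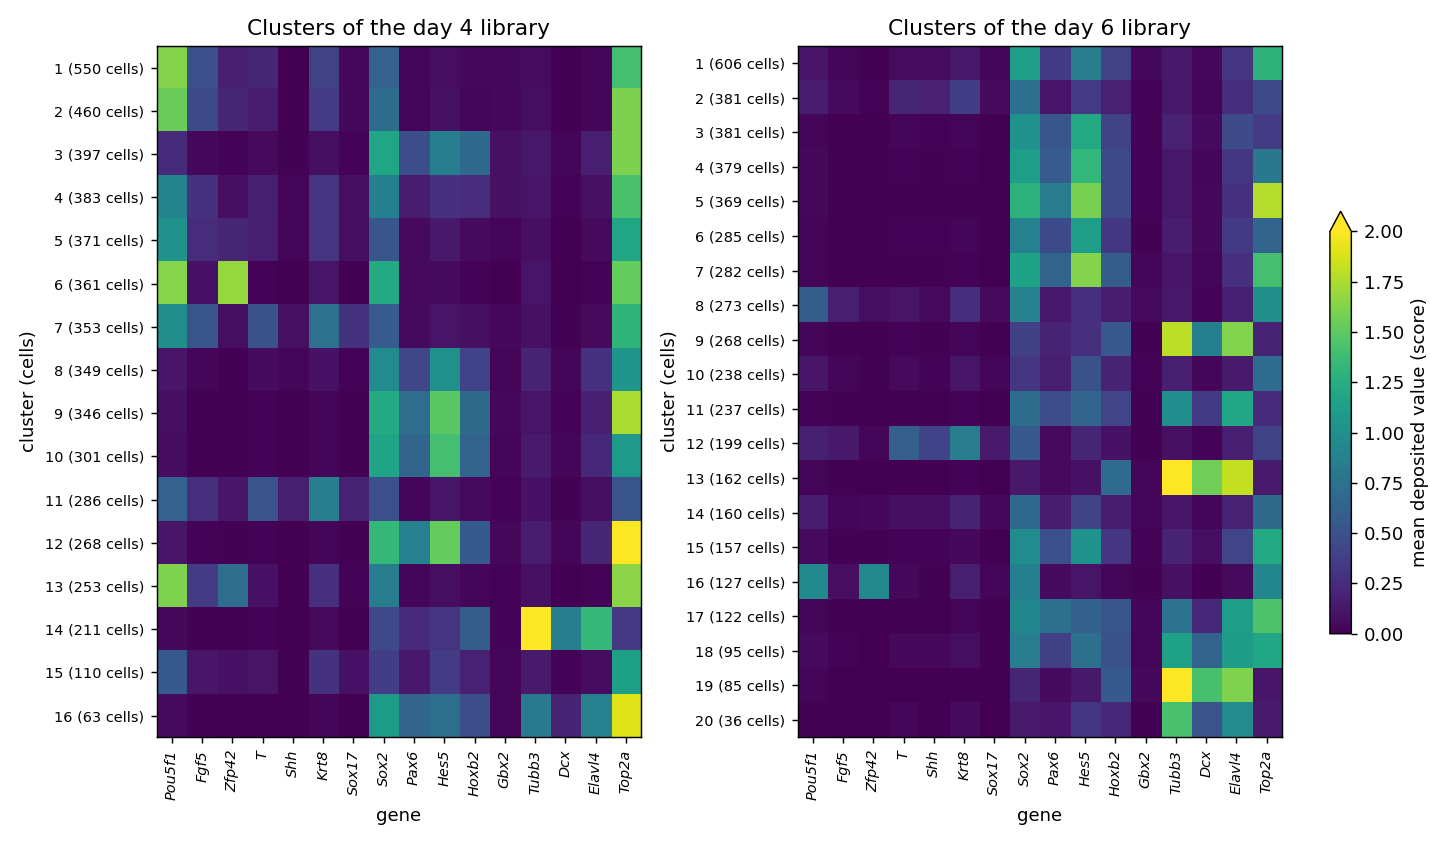
Mean deposited value (colour, score, capped at 2) of 16 genes (x axis) in each cluster (y axis, with its number of cells) of the day 4 library (left) and the day 6 library (right). Pou5f1 reaches 1.64 in cluster 6 of day 4, and Tubb3 reaches 2.34 in cluster 13 of day 6.

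The third comparison set cells of the same named class side by side. The genes given were picked after their values had been seen. Among epiblast-like cells (1010 cells of clusters 1 and 2 at day 4, 273 cells of cluster 8 at day 6), Pou5f1 had means of 1.59 (SD 0.717) and 0.59 (SD 0.43), and Epcam 1.46 and 0.603. Foxa2 had means of 0.151 and 0.243, Sox2 0.664 and 0.885, and Hes5 0.0793 and 0.279. These cells did not cluster together: with both libraries clustered jointly, 99.3% of the day 4 cells but 8.06% of the day 6 cells were in epiblast-like clusters, and 211 of the 273 day 6 cells were in an unnamed joint cluster. In naive pluripotency-like cells (614 cells of clusters 6 and 13 at day 4, 127 cells of cluster 16 at day 6), Pou5f1 had means of 1.63 and 0.958 (a difference of -0.418 after rescaling), and 54.3% of the day 6 cells were in the joint naive pluripotency-like cluster. Zfp42 had means of 1.68 and 0.715 in clusters 6 and 13 of day 4 and 0.939 in cluster 16 of day 6, so no direction is given. The directions of Sox2, T and Klf2 turned with the scaling in this class. In the joint node and notochord-like cluster (146 day 4 and 148 day 6 cells), T had means of 0.778 and 0.697, Shh 0.252 and 0.46, Krt8 1.03 and 0.894, and Pou5f1 0.513 and 0.144. After rescaling, the differences of T (0.102) and Krt8 (0.0997) in this joint cluster turned, so no direction is given for them.

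The fourth comparison asked which genes went with T from cell to cell, by Spearman correlation within each library, over 95 marker genes and 40 lists at day 4 and 77 genes and 39 lists at day 6. Cells are not replicates, and any smoothing of the values before deposit would raise such correlations. At day 4, T went with Sp5 (0.797), Gsc (0.783), Cer1 (0.772), Fgf8 (0.764) and Krt8 (0.757), and against Pax6 (-0.542). At day 6, T went with Sox17 (0.76), Krt19 (0.727), Six3 (0.72), Sp5 (0.709) and Krt8 (0.704), and against Hoxb2 (-0.436). Shh, a notochord gene, had 0.493 at day 4 and 0.681 at day 6. List members here needed a mean of at least 0.02 in that library, and T was left out, so a list could differ between days. The primitive streak list had 8 genes at day 4 and 5 at day 6, and the epithelial list 14 and 9. Wnt ligands had 6 and 4, and general pluripotency 12 and 8. A difference between the days in such a list may thus reflect its members. The correlation of T with the definitive endoderm list was 0.778 at day 4 and 0.657 at day 6, with the node and notochord list 0.735 and 0.647, with the epithelial list 0.608 and 0.758, and with the primitive streak list 0.72 and 0.293. With the neuroectoderm list it was -0.408 and -0.418, with Hox paralogs 1 to 4 -0.419 and -0.569, with the mesenchymal list -0.392 and -0.246, and with Wnt ligands 0.108 and -0.406. The Wnt ligand value turned to -0.0353 at day 4 when partial on the total, and was -0.181 at day 6 by Pearson's method. The correlation of T with the general pluripotency list was 0.367 and 0.312, but 0.011 and 0.0566 by Pearson's method. Over all correlations, 59 of 95 genes and 22 of 40 lists at day 4 and 42 of 77 genes and 21 of 39 lists at day 6 moved by 0.1 or more by Pearson's method.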

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

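Medians over cells, quantile matching, the size rules of 0.1 and 0.5 and names without the limit were chosen after seeing the data. Of 354 alternative values of the lists, 294 kept their sign and their place inside or outside the central 95% of random lists, and no list outside it changed sign. The 24 genes named by rank kept their direction, and 25 of their alternative differences moved by over 1.5 times. The difference of T was -0.0468 by medians over cells. The counts of genes at least 0.25 higher at day 6 and at day 4 were 335 and 135 after rescaling, 253 and 157 with equal totals, 275 and 131 with totals without ribosomal and mitochondrial genes, and 203 and 188 after quantile matching. They were 222 and 2278 at 0.1, 9 and 98 at 0.5, and 0 and 39 for a ratio of at least 4 among the 7000 highest genes.

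Of lists outside the central 95%, 3 came inside: paraxial mesoderm (0.000518 with no minimum level), endothelium and blood (-0.0115 by medians, -0.00424 with no minimum) and germ cells (-0.0303 back-transformed, -0.00977 by medians, -0.0157 quantile-matched). Lists that came to lie outside are given in the order rescaled, equal totals, totals without ribosomal and mitochondrial genes, quantile-matched: definitive endoderm (-0.0151, -0.0145, -0.0143, -0.0161, and -0.0192 by medians) and secreted inhibitors (-0.0227, -0.0227, -0.0222, -0.0238, and -0.029 with no minimum). Others were lateral plate mesoderm (0.00759 by medians, 0.00349 with no minimum), Wnt targets (-0.0939) and FGF ligands and receptors (-0.103) with members at 0.1 or more, G2 and M phase (-0.251 by medians) and retinoic acid response (0.0228 by medians, 0.0979 with members at 0.1 or more).

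Lists inside the central 95% changed sign as follows, in the same order of settings: caudal epiblast (0.0188, 0.00771, 0.0123, 0.0304, and 0.00849 with members at 0.1 or more), node and notochord (0.00915, 0.000126, 0.00158, 0.00875), BMP targets (0.0746, 0.0431, 0.0501, 0.0891), cholesterol synthesis (0.0519, 0.0267, 0.0348, 0.0487), ribosomal proteins (0.528, 0.427, 0.474, 0.00329) and mitochondrially encoded genes (0.337, 0.245, 0.278, 0.0494). Glycolysis did so in the first 3 (0.0658, 0.0326, 0.0445), oxidative phosphorylation when rescaled (0.0249), and extracellular matrix when rescaled (0.00763) or quantile-matched (0.00642). Visceral endoderm changed by medians (-0.00319) and with no minimum (-0.00118), feeder genes with no minimum (0.00239), and retinoic acid response in filtered cells (-0.000587), back-transformed (-0.0217) and with no minimum (-0.00205). The cause was not tested.

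Shares of day 4 cells moved beyond their interval as follows. Naive pluripotency-like cells made up 10.3% at resolution 0.4, 8.4% with fewer variable genes and none of the cell cycle, 8.59% in filtered cells and 9.8% in joint clustering. Node and notochord-like cells made up 4.05% at resolution 1.2, 4.5% with fewer genes and 2.88% jointly. Epiblast-like cells made up 22.2% at resolution 0.4, 21.4% at 1.2, 18.3% with fewer genes, 21.5% with seed 1 and 29.8% jointly. Primitive streak-like cells made up 0% with the limit for names and 7.57% without it. No main cluster was neuroectoderm-like, but such clusters held 12.1% at resolution 0.4, 4.76% with fewer genes, 4.9% with seed 1, 5.07% in filtered cells and 18% jointly. At day 6, naive pluripotency-like cells made up 2.17% with fewer genes and 1.45% jointly, and epiblast-like cells 7.83% at resolution 0.4, 8.53% with fewer genes and 1.65% jointly. Joint clustering also gave 3.06% node and notochord-like and 0.145% neuroectoderm-like cells at day 6, classes with no main cluster there. Unnamed joint clusters 5, 16, 17, 18 and 19 held 555, 294, 317, 315 and 264 day 6 cells. Neuroectoderm was their best class, but with 1 or 2 markers, under the 3 needed for a name. Leading genes were ranked against all other cells, so markers shared by many clusters may lead none. The 0.145% is therefore no measure of neural cells at day 6. The cause was not tested.

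Over all correlations with T of at least 0.1 in size, 13 genes and 4 lists at day 4 and 2 genes and 0 lists at day 6 changed sign by Pearson's method, among them the naive pluripotency list at day 4 (0.403 to -0.0912). Partial on the total, 4 lists at day 4 and 1 at day 6 changed sign, and no gene did. Of the lists picked for naming, those that moved by Pearson's method were the epithelial (0.401 at day 4, 0.579 at day 6), mesenchymal (-0.200, -0.104) and general pluripotency lists (0.011, 0.0566), and, at day 6 only, node and notochord (0.818), Hox paralogs 1 to 4 (-0.421) and Wnt ligands (-0.181). Of the genes picked for naming, 13 values moved by Pearson's method, without a change of sign: at day 4 Cer1 (0.671), Fgf8 (0.546), Gsc (0.662), Krt19 (0.58), Pax6 (-0.353), Shh (0.669), Six3 (0.548) and Sp5 (0.691), and at day 6 Fgf8 (0.438), Hoxb2 (-0.324), Shh (0.786), Six3 (0.595) and Sox17 (0.58). Partial on the total, general pluripotency at day 4 had 0.264 and Wnt ligands changed sign (-0.0353). In naive pluripotency-like cells 9 of 36 genes compared changed sign after rescaling (T, Krt8, Sox2, Egr2, Dcx, Tubb3, Lefty1, Klf2 and Dppa3), against 1 of 36 in epiblast-like cells (Olig3) and 4 of 36 in the joint node and notochord-like cluster (T, Foxa2, Krt8 and Egr2). Of the 10 genes run under every alternative in the naive class, 3 changed sign: Sox2 (0.0316 with equal totals, 0.026 rescaled), T (0.00573 and 0.0026) and Klf2 (0.199 and 0.208, and 0.0407 by medians). The cause was not tested. Thinning, molecule minimums, CPM minimums and doublet removal were not run, because they need counts. The joint epiblast-like and naive pluripotency-like classes held 80 and 70 day 6 cells, under the planned minimum of 100, so the comparison within them was not repeated. No paired analysis was possible because there was 1 library per day.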

Other observations

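Of the tests in this part, the share of the summed values held by the most abundant genes was set out before its result was seen, and the others were chosen after the pattern had been seen. Of 22 G2 and M phase genes 21 were lower at day 6, and 19 after rescaling (median -0.161, percentile 9.59), with Top2a at 1.37 and 0.828. Oxidative phosphorylation genes were lower for 18 of 19 members as deposited, but 12 were higher after rescaling (percentile 17.1), and cytosolic ribosomal proteins turned likewise, from 30 to 67 of 80 higher (percentile 95.8). Glycolysis genes were lower for 11 of 13, with 9 higher after rescaling (percentile 12.3), although Pgk1 was higher as deposited (0.332 and 0.467) and Hk2 lower (0.455 and 0.242). The noncoding RNA Malat1, named after its values were seen, had means of 3.06 and 3.85. The other lists lay inside the central 95%, with medians of 0.00653 (lateral plate mesoderm), -0.0217 (caudal epiblast), -0.00993 (BMP targets), -0.0354 (FGF and ERK targets), 0.000593 (retinoic acid response), -0.0415 (extracellular matrix), -0.108 (DNA methylation enzymes), -0.0506 (hypoxia), -0.0819 (cholesterol synthesis), -0.0611 (dissociation stress), -0.0509 (integrated stress response), -0.0722 (p53 targets), -0.0304 (secreted inhibitors), -0.0105 (Wnt ligands), -0.0302 (FGF ligands and receptors) and -0.0806 (mitochondrially encoded).

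The neuronal genes named by rank may be part of a wider group. A second neuronal list of 30 genes was written after the cluster genes had been seen and was run in 2 versions. Without genes already named and low genes, 26 were used, with a median difference of 0.0486 at percentile 100 of matched random lists. Genes leading a cluster were then left out as well, and of the remaining 18 genes 16 were higher at day 6 (median 0.042, percentile 100). This argues against the 12 named genes alone carrying the difference, and the shift of a wider neuronal group remains a hypothesis without a replicate.

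Single values of abundant genes scattered widely between cells. Rps19, a ribosomal protein gene, had a mean of 3.73 and an SD of 1.68 at day 4, with 95% of cells between 0.61 and 6.63. Depth differences left in the values would move abundant genes together, but the median pairwise correlation of the 100 most abundant genes was at most 0.00511. Scaling of each cell before deposit would remove such movement, so this value does not show how the depth of the cells differed. Counting noise would be smaller in abundant genes on a log scale, but their median SD was at least 2.4 times that of genes with a mean near 1. The scale of the scores is not given, and on a linear scale counting noise would grow as the square root of the mean. The SDs grew faster than that. At day 4 they were 1.31 and 0.511 at median means of 2.87 and 0.996. At day 6 they were 1.26 and 0.526 at median means of 2.74 and 1. The SDs therefore argue against counting noise alone on a log or a linear scale, and decide nothing for other scales. Only 0.0362% of entries at most were 0, which is consistent with values filled in or altered entry by entry before deposit, a step that the sources used here do not describe. No biological explanation was tested.

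Most genes had a lower mean at day 6. Without the 229 day 4 and 38 day 6 cells that missed the quality limits, 73.1% of genes were lower. The limit on totals was set around each library's own median, so it could not take out low totals shared by many day 6 cells. This filter therefore does not decide whether cells of poor quality were the cause. The 100 most abundant genes held 8.11% of the summed values at day 4 and 9.58% at day 6, a gain of 1.47 points. The bound of 5 points set beforehand cannot decide, because the scale is not given and log-type scores would compress the share of abundant genes. A few genes taking more of each total therefore stay open as well. Lower totals per cell at day 6 are also open. With each cell scaled to 1 total, 51.1% of genes were lower, but equal totals centre the genes by themselves, so this value decides nothing, and day and library are the same.

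T stayed high in cluster 12 at day 6. Leftover epiblast-type cells would carry Pou5f1, but its mean there was 0.292 of that in the epiblast-like cluster of the same day. Other genes lay closer, with Fgf5 at 0.134 against 0.164 in the epiblast-like cluster and Fgf8 at 0.172 against 0.176. Pou5f1 alone therefore does not settle whether such cells were the source. A candidate explanation is a node or notochord type, since Shh and Krt8 were high in the cluster, and it remains a hypothesis found and tested on the same data. Droplets that held 2 cells of other clusters could not exceed both cells. All 7 members of the node and notochord list used had a higher mean in cluster 12 than in every other day 6 cluster. Shh was at 0.404 against at most 0.186, and Sox9 at 0.342 against at most 0.298. However, cluster 12 was picked for its T, and the node and notochord list went with T from cell to cell (0.647). Single cells of other clusters can also exceed their cluster's mean, so these means do not exclude such droplets. The comparison of cluster means replaced a test on the median total (106% of the library's), which decides nothing because totals of normalized values need not be higher in such droplets.

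The barcodes in each table ran in 16 alphabetically ordered stretches, of 59 to 1159 cells at day 4 and 96 to 649 at day 6. Mean Pou5f1 of a stretch ran from 0.083 to 1.52 at day 4 and from 0.0304 to 0.962 at day 6. The adjusted Rand index of the stretches with the clusters was 0.192 at day 4 and 0.122 at day 6, against at most 0.00155 and 0.00157 in 100 shuffles. The stretches were not used in any comparison.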
